A study of Mus musculus with 6 samples.

How the data were processed

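Total RNA of 6 mouse whole-lung samples at E18.5, 3 controls and 3 with Scap deleted in respiratory epithelial cells, was purified on RNeasy columns, labelled with biotin after Affymetrix protocols and hybridised to MOE430 V2 arrays, per the labels' protocols and the series design text. Groups and replicate numbers were taken from the sample titles.

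The authors deposited 1 table of intensity values, a linear signal for each of 45101 probe sets on each of the 6 arrays. Per the submitters' processing notes the tool was RMA, but the values do not have the form RMA gives: they are linear rather than log2, reach down to 0.2, and are not quantile normalized. The mean of each array after trimming 2% at either end is 1500, so the arrays look scaled to a common trimmed mean; which software did this, and any background correction, is not given in the sources used here. The column medians were 509.2, 530.5 and 490.9 in control replicates 1 to 3 and 513, 503.2 and 498.5 in Scap-deleted replicates 1 to 3. No gene-wise centring was seen, and single-channel signals have no ratio direction. No detection calls were used here, so whether a dim probe set lies above background is not known, and the linear scale of dim values makes their log2 differences noisy.

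The log2 of the signal was taken without a pseudocount. The 64 Affymetrix control probe sets were left out. Of the other 45037, 34945 carried 1 gene symbol in the platform annotation, 932 several and 9160 none; only those with 1 symbol were named. Entrez IDs of 34741 were found in the mouse gene table of assembly GRCm38.p6, and 0 symbols changed. Each of 18193 genes was represented by its probe set of highest mean over all 6 arrays; 9010 genes had more than 1 probe set, and it is stated where another probe set of a named gene, above the brightness limit, turns direction or shows less than 50% of the log2 difference. Genes whose mean lay below the median of all probe sets (a signal of 497.8) were not tested, which left 10972 genes and set aside 7221.

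Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate and 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Exact two-sided permutation tests were used for Scap. Lists of genes for pathways and cell types were fixed before the data were examined: 29 lists with 451 memberships, of which 416 had a probe set and 338 were tested. Of them 25 lists with at least 4 tested genes were tested by camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera also uses the residual degrees of freedom, far fewer than with the preset one. A p-value "with an estimated correlation" thus differs on both counts. The sex-linked list was used only to look at the makeup of the samples; the lists of airway basal and neuroendocrine cells (1 tested gene), of erythroid cells (3) and of thymus, liver and oesophagus (0) were too small to test. A count "adjusted over the list alone" applies Benjamini-Hochberg within that list.

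The genes named in the text follow a rule set before the data were examined: Scap; per direction, up to 8 genes past the threshold with no overlap of the groups, filled up to 8 with those of smallest p; up to 4 members of smallest p from each list past the list test and up to 1 at an unadjusted p of 0.05 from each other list; and 12 reference genes, of which 2 had no probe set with a single symbol and were not analysed here. Symbols of unnamed clones were passed over. This gave 54 tested genes and Pparg. Hspa5, Xbp1, Krt15, Alas2, Epcam, Elf5, Mt1 and the genes of the closing observations were chosen after their values were seen.

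The titles give both groups the numbers 1 to 3. Deviations from the group means correlated across genes at 0.17, 0.20 and 0.43 between samples of the same number, all above 0.1, so the numbers were taken to pair the samples; the pairing comes from the data and from the titles, and what a number stands for is not given in the sources used here. Of other pairs, control 2 with Scap-deleted 1 reached 0.18, above the 0.17 of the pair numbered 1. Deviations within a group cancel out, so arrays numbered 3 that stand apart make the remaining arrays correlate whatever their numbers. The correlations thus bear mainly on number 3, and for numbers 1 and 2 the pairing rests on the titles. Values with the replicate number as a block are given where they change a call or a count of calls named in the text. The first principal component, 36.6% of the variance, set the arrays numbered 3 of both groups apart from the other 4, and the second, 21.1%, separated the groups. Array correlations lay between 0.969 and 0.984. No scan date or other batch is given in the sources used here.

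The steps were tested on simulated data with the real genes' means and spreads for this comparison, 10972 genes and 20 runs with 200 genes changed. The fit recovered 41.2% of genes changed 1.5-fold, 76.6% of those changed 2-fold and 96.7% of those changed 4-fold, with 5.11% false among those called. Noise was drawn independently for each gene and array, and the recovered shares depend on how many genes are changed. They need not hold for the real data, where Scd1 at 16.5% of control was not called. Simulated lists of 15 genes shifted by 0.4 log2 were found in 100% of runs and unshifted lists called in 0%, without correlation between genes, which real lists have.

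Alternatives were: no filter on dim genes and a filter at the 75th percentile; quantile normalization and centring on array medians; the mean of a gene's probe sets, and leaving out probe sets that can match several transcripts; a fit on probe sets; eBayes with trend and robust settings; array weights; the replicate block; an adjusted p of 0.1, and an unadjusted p of 0.05 with a fold of at least 1.5; leaving out each array in turn; and lists without shared members. After the data were seen, a pseudocount of 100, leaving out both arrays numbered 3, trend and weights for the lists, and the surfactant list without Abca3 and Lpcat1 were added.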

Results

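The series profiled transcripts of whole mouse lung at E18.5, close to birth, on 6 MOE430 V2 arrays. In 3 samples the Scap gene had been deleted from respiratory epithelial cells, and 3 samples were controls, all on a mixed FVB/N and B6 background. Scap encodes the escort protein that carries the SREBP transcription factors from the endoplasmic reticulum to the Golgi, where they are cleaved and released to switch on genes of sterol and fatty acid synthesis. The comparison asks which lung transcripts differ when this pathway is interrupted in the epithelium, and the series title draws attention to lipid homeostasis and to lipofibroblasts. Array medians lay between 490.9 and 530.5 signal units and the highest signals between 101398 and 128538. The number of arrays limits the precision of every comparison. Nothing in the labels says that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical. Values below are mean signal ± SD with n = 3 arrays per group, log2 differences are Scap-deleted minus control with the standard error (SE) from limma, and adjusted p is Benjamini-Hochberg over the 10972 genes tested unless another family is named.

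The targeted transcript itself was lower on average in the Scap-deleted lungs, and the groups overlapped. Scap signal was 4846 ± 2167 in controls and 2612 ± 724 in Scap-deleted lungs, 55.9% of control on the log2 scale (log2 difference -0.84, SE 0.33, limma adjusted p = 0.808). The control arrays read 7264, 4195 and 3080, and the Scap-deleted arrays read 1847, 3286 and 2702. An exact two-sided permutation test gave p = 0.2 for this probe set, where 0.1 is the smallest p that 3 against 3 arrays allow. Within each pair of samples of the same number the Scap-deleted one read lower. The unadjusted limma p was 0.0371 without the replicate block and 0.0485 with it (adjusted p = 0.567). A second, dimmer Scap probe set read 436.5 ± 315 in controls and 238.6 ± 79.3 in Scap-deleted lungs (exact p = 0.8). The position of these probe sets relative to the deleted part of the gene is not given in the sources used here, and whole lung holds Scap transcript from cells outside the epithelium, so this is a weak check of the labels.

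Of the single genes, 1 passed the threshold. Acox2, a peroxisomal acyl-CoA oxidase that shortens branched fatty acids and bile acid intermediates, rose from 574 ± 39.7 to 1328 ± 48.9 (log2 difference 1.21, SE 0.10, adjusted p = 0.0289). Scd1, the desaturase that makes monounsaturated fatty acids, read 39951 ± 5308 in controls and 7497 ± 4887 in Scap-deleted lungs, a log2 difference of -2.60 (SE 0.39, adjusted p = 0.319). The acyl-CoA oxidase-like gene Acoxl stood at 21.8% of control (log2 difference -2.20, SE 0.29). Derl3, which takes part in degrading misfolded proteins of the endoplasmic reticulum, read 282.8 ± 110 in controls and 1054 ± 174 in Scap-deleted lungs (log2 difference 1.95, SE 0.26); both Acoxl and Derl3 had adjusted p = 0.271. All 4 genes had every Scap-deleted array on one side of every control array.

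Limma called 1 gene higher, Acox2, and 0 lower at an adjusted p of 0.05. At an unadjusted p of 0.05, 316 genes were higher and 334 lower, 650 together against 548.6 given by chance on average. Genes are correlated, so this count varies. The other splits of the 6 arrays, 3 against 3, gave 265 to 1123 such genes, with 743, 746 and 861 also above 650. Groups did not overlap in 670 higher and 628 lower genes, 11.8% of those tested, where chance gives 10%. With the replicate number as a block no gene was called, Acox2 had adjusted p = 0.118, and the smallest adjusted p was 0.0912, with 955 genes at an unadjusted p of 0.05. The Acox2 call was also lost when any single array was left out, with adjusted p from 0.0781 without control replicate 1 to 0.343 without Scap_deleted replicate 1.

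Genes of the SREBP pathway were lower than other genes by camera with a preset correlation of 0.01, adjusted over 25 lists (adjusted p = 4.36e-06; 0.224 with an estimated correlation). Of 10 tested members, 8 had negative differences, and 4 fell when adjusted over the list alone (5 with the replicate block), against 0 over all genes tested. Scap, the deleted gene, is itself a member with a negative difference, and the list was not tested without it. Insig1, which holds Scap in the endoplasmic reticulum and is itself an SREBP target, fell from 3665 ± 860 to 1462 ± 116 (log2 difference -1.30, SE 0.17, adjusted p = 0.000824 over the list alone and 0.271 over all genes). The genes for the transcription factors themselves fell too, Srebf1 to 61.9% and Srebf2 to 68.2% of control (each with adjusted p = 0.00229 over the list alone). Mylip, an LXR-induced ligase that degrades lipoprotein receptors, fell to 70.9%.

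**Figure D1:**
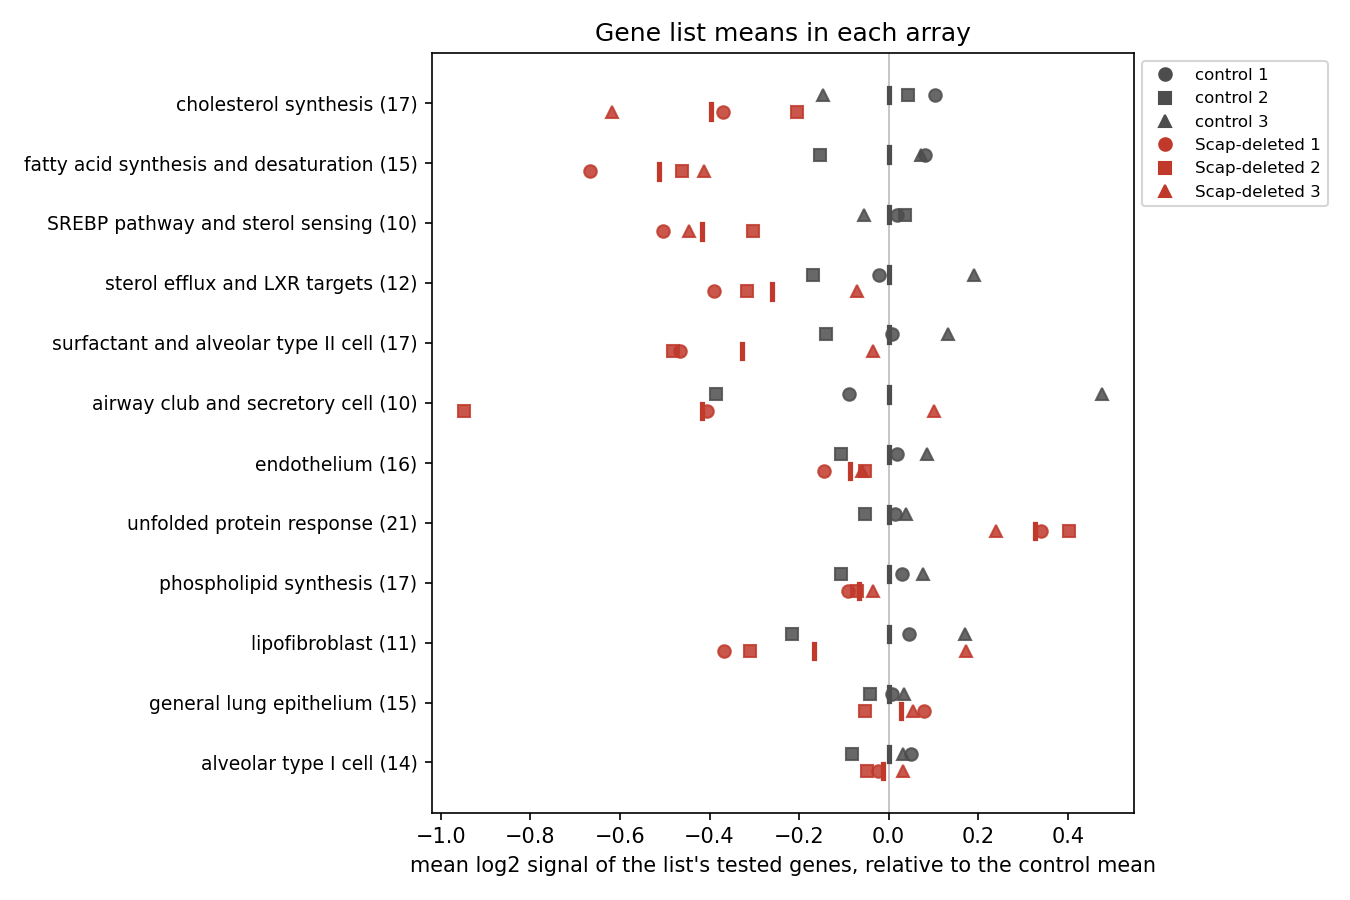
Mean log2 signal of each gene list's tested genes in each of the 6 arrays, relative to the mean of the controls, with the number of tested genes in brackets; short vertical bars are group means and symbols mark the replicate number. In the cholesterol, fatty acid, SREBP and unfolded protein response lists, all 3 Scap-deleted arrays lie outside the range of the 3 controls, while the groups overlap in the surfactant, club cell, sterol efflux and endothelial lists, which also passed the list test, and in the general lung epithelium, alveolar type I and lipofibroblast lists, which did not.

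Cholesterol synthesis genes read lower along the pathway: 16 of 17 tested members had negative differences, the median member stood at 77.1% of control, and 5 fell when adjusted over the list alone. Hmgcs1, the HMG-CoA synthase near the start of the pathway, fell from 14885 ± 1965 to 9915 ± 1169 (log2 difference -0.58, SE 0.14). Fdps, which makes farnesyl diphosphate, fell to 54.4% of control, Tm7sf2 (sterol delta-14 reductase) to 67.3% and Cyp51 (lanosterol demethylase) to 72.5%, each with an adjusted p of at most 0.0367 over the list alone. The count of 5 depended on single arrays: it was 0 without control replicate 1, Scap_deleted replicate 1 or Scap_deleted replicate 3, 2 without control replicate 2, and 8 without control replicate 3 or with the replicate block. It was 8 without both arrays numbered 3, which stand apart from the others in both groups.

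Fatty acid synthesis and desaturation genes moved the same way. All 15 tested members had negative differences, with a median at 78.2% of control, and 7 fell when adjusted over the list alone (8 with the replicate block). Besides Scd1 (adjusted p = 0.00348 over the list alone), they included Fasn, the fatty acid synthase, from 18324 ± 2817 to 10981 ± 1969 (log2 difference -0.74, SE 0.16), Scd2, a second desaturase, to 68.9% of control, and Mid1ip1, an activator of acetyl-CoA carboxylase, to 65.2%.

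**Figure D2:**
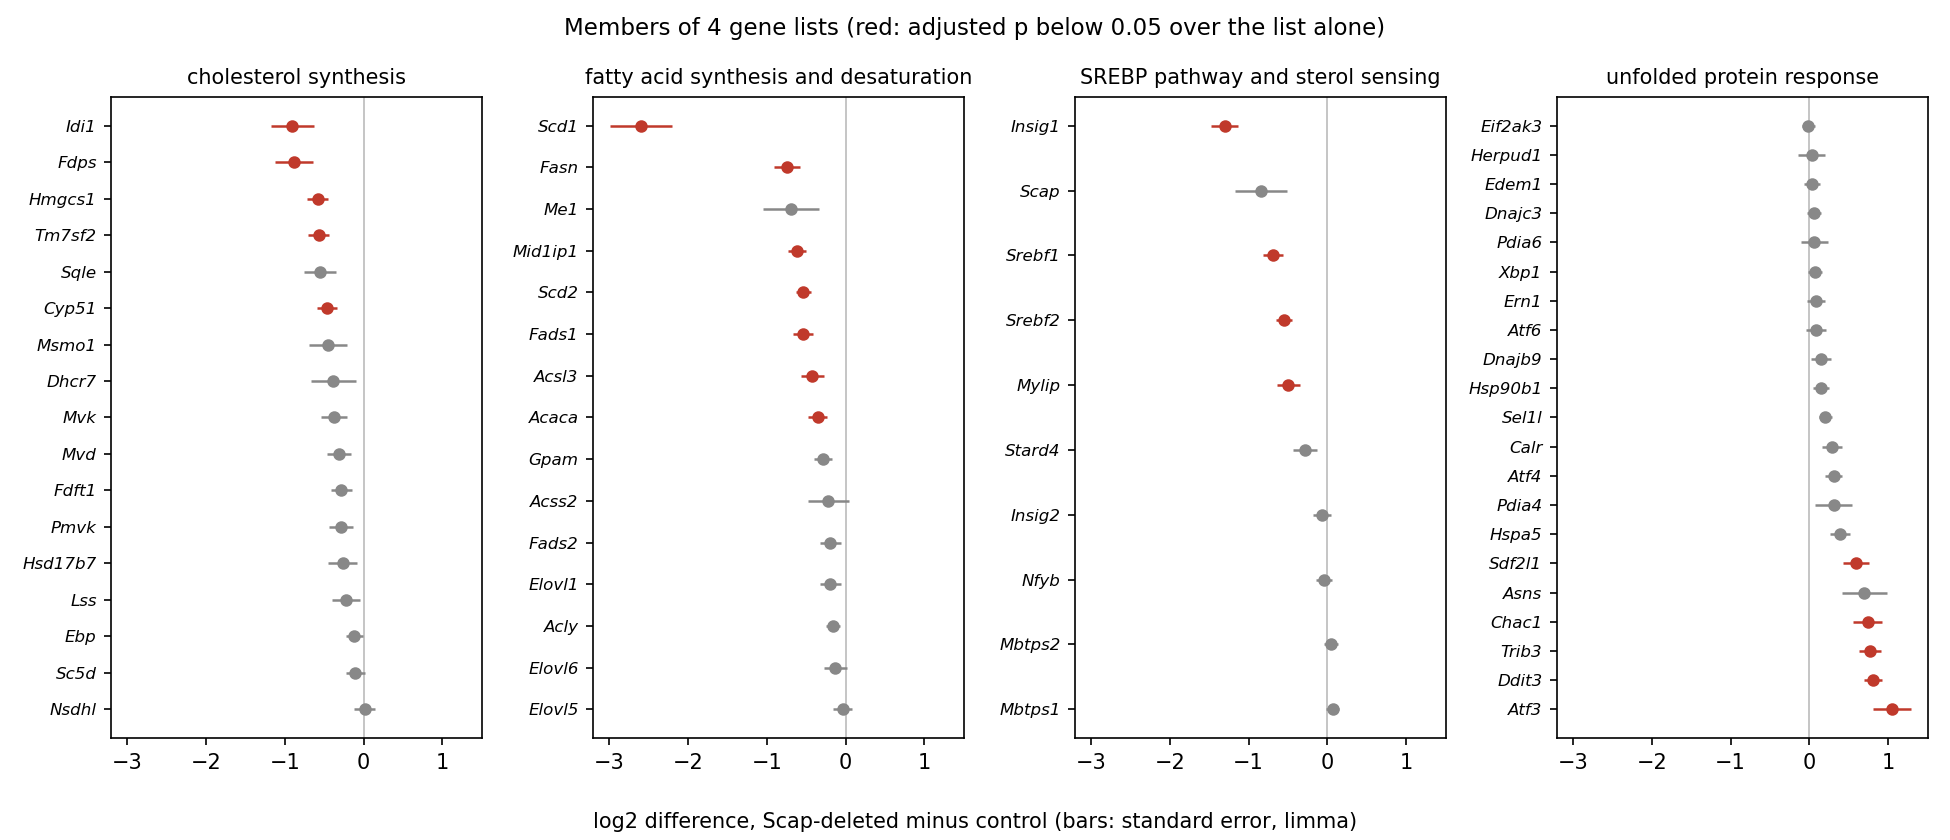
Log2 difference (Scap-deleted minus control) of each tested member of 4 gene lists, with limma standard errors as bars; red marks members with an adjusted p below 0.05 over their list alone. Of the lipid lists, 16 of 17 cholesterol genes and 15 of 15 fatty acid genes lie left of 0, and 20 of 21 unfolded protein response genes lie right of 0.

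By camera, the fatty acid list (adjusted p = 9.23e-12; 0.224 with an estimated correlation) and the cholesterol list (5.74e-10; 0.289) were lower than other genes. As measured on each array, the cholesterol list mean was -0.15 to 0.10 in controls and -0.62 to -0.21 in Scap-deleted lungs.

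Sterol efflux genes and LXR targets were lower as well, with 11 of 12 tested members negative and a median at 85.3% of control (camera adjusted p = 9.53e-05; adjusted p = 0.383 with an estimated correlation). Abca1, the cholesterol exporter, read 18239 ± 1615 in controls and 13459 ± 1512 in Scap-deleted lungs (log2 difference -0.44, SE 0.12). The phospholipid transfer protein Pltp stood at 84.5% and the lysosomal cholesterol transporter Npc1 at 73.7% of control. None of the 12 passed when adjusted over the list alone, and 4 did so with the replicate block.

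In the list of surfactant and alveolar type II cell genes, 14 of 17 tested members were negative, with a median at 89.6% of control. Sftpa1, which encodes surfactant protein A, read 41768 ± 6290 in controls and 20925 ± 12259 in Scap-deleted lungs (log2 difference -1.14, SE 0.35, adjusted p = 0.0562 over the list alone). Abca3, the transporter that loads phospholipid into lamellar bodies, stood at 63.9% of control (SE 0.21 on the log2 scale), although its dimmest probe set read 119.6%. Sftpb, surfactant protein B, stood at 76.5%. Sftpc, surfactant protein C, read 97440 ± 15052 in controls and 97286 ± 6167 in Scap-deleted lungs; its log2 difference of 0.01 (SE 0.13) turned to -0.03 under quantile normalization, and its probe set ranked 6 in brightness among 45037, where a compressed signal would hide a difference, which was not tested.

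Of this list, 2 genes fell when adjusted over the list alone, each with adjusted p = 0.0322: Lyz2, a lysozyme, to 57.7% of control, and Lpcat1, which remodels surfactant phosphatidylcholine, by a log2 difference of -0.41 (SE 0.10). Lyz1, a near-identical lysozyme gene whose probes may read both, stood at 54.7% (log2 difference -0.87, SE 0.12); it entered the leukocyte list, where it was the only member past the list-alone threshold, and the other 12 tested members did not pass it. Hc, the gene of complement factor C5, stood at 65.7%. The list was lower by camera (adjusted p = 1.08e-05; 0.631 with an estimated correlation, again an adjusted p), and the count of 2 became 7 with the replicate block. It was 0 without control replicate 1, Scap_deleted replicate 1 or Scap_deleted replicate 2, 1 without control replicate 3, and 8 without Scap_deleted replicate 3. The median log2 difference of the list, -0.16, became -0.30 without control replicate 2, -0.26 without control replicate 3 and -0.36 without Scap_deleted replicate 3. Surfactant list means were higher in the arrays numbered 3 than in the others of their group, by 0.20 log2 in controls and 0.44 in Scap-deleted lungs.

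**Figure D3:**
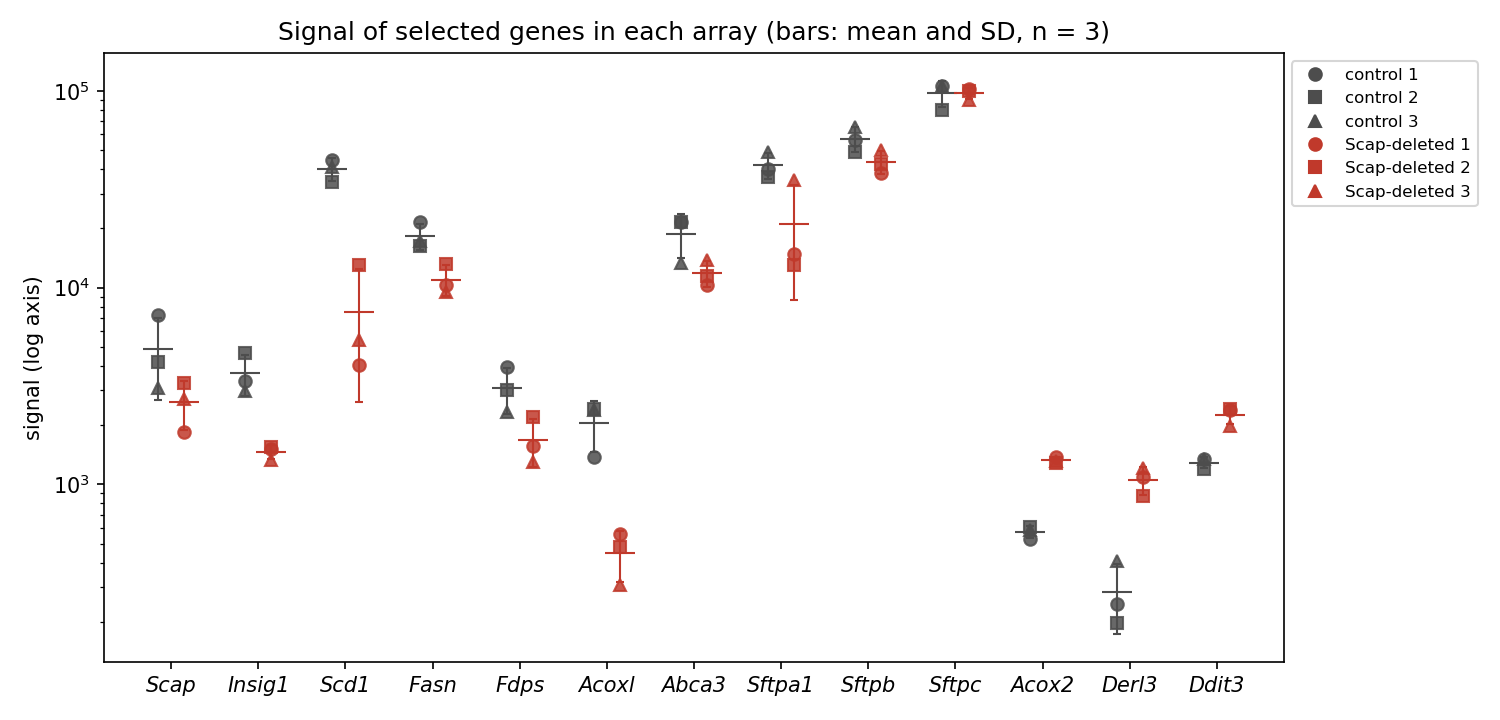
Signal of 13 genes in each of the 6 arrays on a log axis, with bars for the mean ± SD of 3 arrays and symbols for the replicate number. Scd1 reaches 13085 at most in Scap-deleted lungs and lies far above it in every control, while the Sftpc points of both groups overlap near the top of the signal range.

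Airway club and secretory cell genes were lower in all 10 tested members, with a median at 84.0% of control (camera adjusted p = 0.00202; adjusted p = 0.788 with an estimated correlation). Scgb3a1, a secretoglobin of airway secretory cells, read 11160 ± 8924 in controls and 5500 ± 5397 in Scap-deleted lungs, its spread set by high readings in both arrays numbered 3. Scgb3a2 stood at 82.0%, Chad, chondroadherin, at 64.5%, and Sec14l3 at 86.9%. None passed when adjusted over the list alone, and 3 did so with the replicate block. The list's call was lost without control replicate 3 (adjusted p = 0.275) and without Scap_deleted replicate 2 (0.127). The median log2 difference of -0.25 became -0.09 and -0.12 without these, each with 9 of 10 members negative, and -0.38 without Scap_deleted replicate 3. The list means were higher in the arrays numbered 3, by 0.71 log2 in controls and 0.78 in Scap-deleted lungs.

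Endothelial genes showed small negative differences in 12 of 16 tested members, with a median at 92.9% of control (camera adjusted p = 0.0194; adjusted p = 0.669 with an estimated correlation). Cdh5, vascular endothelial cadherin, read 12151 ± 48.3 in controls and 10412 ± 369 in Scap-deleted lungs, and Ramp2, Tie1 and Pecam1 stood between 84.5% and 86.5% of control. With the replicate block the adjusted p was 0.0757, and the call was also lost without control replicate 1 (0.0852), control replicate 3 (0.202) or Scap_deleted replicate 1 (0.177).

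Genes of the unfolded protein response, the programme that cells start when proteins misfold in the endoplasmic reticulum, were higher than other genes by camera (adjusted p = 2.35e-09; 0.224 with an estimated correlation). Of 21 tested members 20 had positive differences, with a median at 115.1% of control, and 5 rose when adjusted over the list alone. Ddit3, the stress transcription factor CHOP, rose from 1289 ± 83.0 to 2258 ± 241 (log2 difference 0.80, SE 0.11, adjusted p = 0.00311 over the list alone). Atf3 rose to 207%, Trib3 to 170.5% and Chac1 to 167% of control, all 3 of them known targets of the ATF4 and CHOP branch. The chaperone gene Hspa5 stood at 131.2% and Xbp1, a transcription factor of another branch of the response, at 105.2%, although its other 3 probe sets read 91.7% to 98.8%; both were named after their values were seen, and neither was past the list-alone threshold.

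The count of 5 unfolded protein response genes was 2 without Scap_deleted replicate 1, 3 without Scap_deleted replicate 2, 8 without Scap_deleted replicate 3, 8 without both arrays numbered 3 and 6 with the replicate block. It was 2 with no filter on dim genes and 0 with the filter at the 75th percentile, which tests 14 of the 21 members and takes the median log2 difference from 0.20 to 0.09.

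Lipofibroblast genes, the focus named in the series title, did not pass the list test (camera adjusted p = 0.160), with 8 of 11 tested members negative and a median at 94.4% of control. Plin2, a coat protein of lipid droplets, read 9985 ± 1112 in controls and 9113 ± 168 in Scap-deleted lungs. Tcf21, a mesenchymal transcription factor, stood at 95.5% (its other probe set read 99.7%), and the fatty acid receptor Cd36 at 75.5% of control (log2 difference -0.40, SE 0.15, adjusted p = 0.792), although its dimmest probe set read 95.1%. Pparg lay below the brightness limit for testing, at 296.3 ± 80.1 and 466 ± 128. The list did pass without both arrays numbered 3 (adjusted p = 0.0138), without Scap_deleted replicate 3 (0.0046) and without control replicate 2 (0.0451).

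Marker lists of the other cell types did not pass the list test. The general lung epithelium list had 10 of 15 members positive and a median at 104.8% of control (adjusted p = 0.472), with Cldn4, a tight junction claudin, at 135.9%. At an unadjusted p of 0.05, 2 of its members were higher and 2 lower; the lower ones, named after their values were seen, were Epcam at 77.3% and Elf5 at 76.6% (its other probe set read 107.9%). The alveolar type I list stood at 102.7% (0.837), the ciliated list at 97.1% (0.681), smooth muscle and myofibroblast at 101.1% (0.638), matrix fibroblast at 99.4% (0.627), leukocytes and macrophages at 111.1% (0.434), heart and skeletal muscle at 108.1% (0.187) and mesothelium, nerve and brown fat at 93.6% (0.538), each as the median member's percent of control with its camera adjusted p. Without Scap_deleted replicate 2 the leukocyte list (adjusted p = 0.00473) and the heart and skeletal muscle list (0.000279) passed as higher. In the ciliated list Tubb4b, a beta tubulin, stood at 119.9%, but its next brightest probe set read 100.9%.

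Of the remaining metabolic and stress lists, none passed. Phospholipid synthesis had a median at 95.4% of control (camera adjusted p = 0.187), lipid uptake, storage and lipolysis 94.9% (0.186), fatty acid oxidation 101.3% (0.638), glycogen metabolism 99.0% (0.715), hypoxia and glycolysis 101.2% (0.715), glucocorticoid response 93.5% (0.475), inflammation 111.4% (0.187) and cell cycle 103.5% (0.538). Leaving out 1 array changed 4 of these: phospholipid synthesis passed as lower without control replicate 2 (0.0287), lipid uptake as lower without control replicate 2 (0.0417) or Scap_deleted replicate 3 (0.00717), inflammation as higher without control replicate 1 (0.0345), and cell cycle as higher without Scap_deleted replicate 3 (8.13e-06), each an adjusted p. Single members stood out: the fatty acid binding protein Fabp5 at 60.0% of control (log2 difference -0.74, SE 0.19), the cell cycle inhibitor Cdkn1a at 152.1% (its other probe set read 121.5%) and the glycogen phosphorylase Pygb at 130.7%, none past the list-alone threshold; with the replicate block Fabp5 and Cdkn1a passed it (adjusted p = 0.00809 and 0.0369), as did Cd36 in the lipid uptake list (0.0449). Icam1, an adhesion molecule, rose to 127.1% when adjusted over the inflammation list alone (adjusted p = 0.0491), which the replicate block took to 0.0761. That call was also lost with no filter on dim genes, under quantile normalization, under centring, without both arrays numbered 3, and without control replicate 1, 2 or 3 or Scap_deleted replicate 1 or 2. In lists too small to test, the only bright basal cell gene, Krt15, read 1619 ± 107 in controls and 680 ± 528 in Scap-deleted lungs (log2 difference -1.96, SE 0.91, unadjusted p = 0.0671, and 0.0333 with the block), a difference carried by the reading of 74.7 in Scap_deleted replicate 3 and of -0.72 without it. All 3 erythroid genes were negative, with a median at 87.2% of control; of these Alas2 passed with the block (adjusted p = 0.0432 over the list alone).

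Besides Acox2, Derl3 and Acoxl, 6 genes outside these lists were named for their small unadjusted p, and these 6 did not pass the threshold over all genes. Higher in Scap-deleted lungs were Thbs1, the matrix protein thrombospondin, at 154% of control (its other probe set read 119.3%), Atf5, a transcription factor of the ATF4 family, at 168.7%, Lsp1, an actin-binding protein, at 147.3% and Arhgap39 at 158.9% (its next brightest probe set read 102.2%). Lower were Pcdh18, a protocadherin, at 63.9% (log2 difference -0.65, SE 0.10) and Nmnat2, which makes NAD, at 68.3%. The adjusted p of these 6 genes ran from 0.279 to 0.505.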

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

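The pseudocount, leaving out both arrays numbered 3, trend and array weights for the lists, and the surfactant list without Abca3 and Lpcat1 were chosen only after the results were seen. In every setting run the median log2 difference of all genes stayed within 0.02 of 0, and 52 of 54 named genes kept their direction. The exceptions were Sftpc, at -0.03 (-0.0326) under quantile normalization, -0.03 (-0.0334) under array weights and from -0.13 to 0.08 (0.0768) when each array was left out, and Arhgap39, at -0.05 (-0.0540) with the mean of a gene's probe sets, which brings in its disagreeing probe sets. Since no detection calls were used here, whether a dim gene lies above background is not known, which limits what the setting with no filter can show. Every array read 1399 to 54266 over the Xist probe sets and at most 203.9 over the Y-linked ones, so no sample stood out by sex and the planned sex covariate was not run.

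The count of higher genes, 1 as reported, was 0 with no filter on dim genes, with the filter at the 75th percentile (where Acox2 is not tested), with trend and robust settings, with the replicate block, at probe set level and without both arrays numbered 3. At an unadjusted p of 0.05 limma gave 415 to 1062 genes in the gene-level settings among these. The count was 2 without x_at and s_at probe sets, where a second probe set took the place of the reported one for Mt1 (log2 difference 2.51, adjusted p = 0.0480; 0.11 and 0.971 as reported). Leaving out each array gave 0 higher genes each time and 0 to 1 lower genes, the latter being Scd1 without Scap_deleted replicate 2 (adjusted p = 0.0127), with 510 to 766 genes at an unadjusted p of 0.05. Over all alternatives that tested it, Acox2 kept its direction, with adjusted p from 0.0130 to 0.343. An unadjusted p of 0.05 with a 1.5-fold difference gave 42 higher and 49 lower genes. Where arrays or genes were left out, fewer data entered; for the other settings the cause was not tested.

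The 8 list calls kept their direction in all 161 alternatives and were lost in 25. With an estimated correlation 0 of 25 lists passed, and 0 by fry, which asks whether a list differs from no change and not from other genes. The median log2 difference of all genes was 0.005, so both questions lie close here. The 8 of the 25 losses that came from fry therefore count against the calls too. The adjusted p values with an estimated correlation were 0.289 for cholesterol synthesis, 0.224 for fatty acid synthesis, for the SREBP pathway and for the unfolded protein response, and 0.631 for surfactant; fry gave 0.241, 0.0699, 0.0660, 0.0699 and 0.496 for the cholesterol, fatty acid, SREBP, unfolded protein response and surfactant lists. The estimated correlations of the 8 lists, 0.0882 to 0.805, exceed the preset one, which widens that test by construction; for fry the cause was not tested. Besides these, the club cell list was lost with no filter (0.0844), and the endothelial list with no filter (0.0939), the replicate block (0.0757) and without both arrays numbered 3 (0.284). The block changed no other list call. The remaining losses came with single arrays left out, 2 for the club cell list and 3 for the endothelial list. Counts over the list alone ranged over the alternatives from 0 to 8 for cholesterol, 5 to 9 for fatty acid, 3 to 5 for SREBP, 0 to 8 for surfactant and 0 to 9 for unfolded protein response genes. A count of 0 arose with no filter for cholesterol and surfactant, with the 75th percentile filter for unfolded protein response, with centring for surfactant, and with single arrays left out for cholesterol and surfactant. The surfactant list without Abca3 and Lpcat1 kept its call (0.000494).

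Lists that were not called passed in 14 of 339 alternatives. The lipofibroblast list passed with array weights (adjusted p = 0.0365) and without both arrays numbered 3 (0.0138), and ranged from 0.0046 to 0.501 when each array was left out; its direction was kept. Besides lists passing with a single array left out, phospholipid synthesis passed with the mean of probe sets (0.0158), lipid uptake with the 75th percentile filter (0.00167) and cell cycle without both arrays numbered 3 (0.00129). Directions of uncalled lists turned as follows, in adjusted p. The alveolar type I list turned with no filter (0.833) and quantile normalization (0.957), smooth muscle with the mean of probe sets (0.481) and array weights (0.949), matrix fibroblast with the mean of probe sets (0.947) and without the arrays numbered 3 (0.989), hypoxia with array weights (0.669) and without those arrays (0.770), and inflammation without those arrays (0.446). With each array left out, lists whose direction turned ranged as follows: alveolar type I 0.589 to 0.960, ciliated 0.346 to 0.976, fatty acid oxidation 0.254 to 0.976, smooth muscle 0.219 to 0.937, matrix fibroblast 0.0535 to 0.976, leukocytes 0.00473 to 0.727, inflammation 0.0345 to 0.988, cell cycle 8.13e-06 to 0.908, glycogen 0.583 to 0.908, hypoxia 0.319 to 0.640, glucocorticoid 0.103 to 0.951 and mesothelium 0.214 to 0.864. The cause was not tested.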

Other observations

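The tests of epithelial share and of lung maturity were chosen only after the result they measure was seen. The lists of ATF4 targets, multiciliated commitment genes and immediate early genes were drawn up after the main results and before their own values were looked at, except that Dusp1, 1 of the 17 immediate early and heat shock genes tested, had been seen.

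Further genes known as targets of ATF4, the transcription factor that raises amino acid supply under stress, leaned higher in Scap-deleted lungs: 24 of 27 tested were positive, with a mean log2 difference of 0.14 (SE over genes 0.03). Slc7a1, a transporter of cationic amino acids, stood at 156.4% of control, the stress gene Nupr1 at 148.4% and the alanyl-tRNA synthetase gene Aars at 135% (its other probe set read 113.9%). These were the largest differences of the 27, whose median log2 difference was 0.09. By limma, 0 passed when adjusted over the list alone, and 3 had an unadjusted p under 0.05, Slc7a1 and Aars among them. For Nupr1 the unadjusted limma p was 0.103.

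Deup1 and Ccno, which multiply centrioles in cells about to grow many cilia, stood at 187% and 179.7% of control (log2 differences 0.90, SE 0.17, and 0.85, SE 0.24; limma adjusted p = 0.551 and 0.731). A hypothesis is that more cells were committing to the multiciliated fate. Other genes of that step were listed because Deup1 and Ccno read high in these same arrays, so genes that vary with them may move along whatever the cause. Of the 14 listed, 9 were bright enough to be tested, and 9 of 9 were positive, Rfx2 at 140.7% and Sass6 at 126.4% among them. Their mean log2 difference was 0.28 (SE over genes 0.07, which does not measure the spread between lungs). Camera gave p = 0.000233 with a preset correlation and p = 0.0269 with an estimated correlation. This may be read as consistent with the hypothesis, with limits: 0 of the 9 passed by limma when adjusted over the list alone (3 had an unadjusted p under 0.05), Plk4, Stil, Sass6 and Cep152 also serve centriole copying in any dividing cell, and Foxj1, the master gene of ciliated cells, stood at 98.0%.

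The lower sterol and fatty acid synthesis lists had a mean log2 difference of -0.45 (SE over genes 0.08). Fewer epithelial cells in the Scap-deleted lungs would lower epithelial genes too. The general lung epithelium list had a mean of 0.03 (0.0269, SE over genes 0.06). That SE is over genes of the same 6 arrays and does not measure the spread between lungs. By array the list mean was -0.04 to 0.03 in controls and -0.05 to 0.08 in Scap-deleted lungs. In Scap-deleted lungs the cholesterol list ran from -0.62 to -0.21 and the fatty acid list from -0.67 to -0.41. This argues against a loss across the epithelium as large as the fall of these lipid lists, and a smaller loss stays open. Members of the general list went both ways, with Epcam at 77.3% and Cldn4 at 135.9%. The lists of surfactant and alveolar type II genes (mean -0.33) and of club and secretory genes (-0.42) were lower too, so fewer cells of those epithelial types stay open, which was not tested. Array scaling would shrink the median of both lists to near 0, and it stayed at -0.35 (-0.351) under quantile normalization or centring. A direct loss of SREBP activity in the epithelium, which the design gives as the biological explanation, stays open as a hypothesis, as does a response of other cells, since whole lung was measured.

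For the higher unfolded protein response list, with a mean log2 difference of 0.33 (SE over genes 0.07), stress at dissection would raise immediate early and heat shock genes too. Their mean was 0.02 (0.0214, SE over genes 0.04), with 11 of 17 positive and a camera p of 0.876 with a preset correlation. This argues against handling as the whole cause. The SE is over genes of the same 6 arrays and does not measure the spread between lungs, so a smaller part for handling stays open. An ATF4 programme in the Scap-deleted lungs is a candidate explanation: the further ATF4 targets above gave a camera p of 0.000103 with a preset correlation, and p = 0.0836 with an estimated correlation. The outcome turns on which camera setting is used, and the one with an estimated correlation also works with only 4 residual degrees of freedom. This test therefore does not decide on an ATF4 programme. Whether the shift reaches beyond ATF4 targets was not tested.

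The arrays numbered 3 stood apart in both groups on the first principal component, at 0.59 and 0.55 against -0.35 to -0.14 in the other arrays. Relative to the others of their group they read higher in club cell genes (by 0.71 log2 in controls and 0.78 in Scap-deleted lungs) and surfactant genes (0.20 and 0.44), and lower in cell cycle genes (-0.45 and -0.71). All 3 of these lists moved as in a more mature lung, but they were picked after they were seen to move, so greater maturity stays open and is not supported by this count. Other lists moved too, leukocytes by 0.34 and 0.42, lipofibroblast by 0.26 and 0.51, sterol efflux by 0.29 and 0.28 and cholesterol by -0.22 and -0.33, while alveolar type I stood at 0.05 and 0.07. Heart or other tissue carried over at dissection stays open: the heart and skeletal muscle list was higher by 0.10 and 0.16, the smaller only 1.07 standard errors over genes. The mesothelium, nerve and brown fat list was higher by 0.24 (SE over genes 0.13) in controls and 0.37 (0.19) in Scap-deleted lungs.

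Among the 10 ways to split the 6 arrays 3 against 3, 2 gave as many genes as the real grouping's 1 (highest other 1) and 3 gave as many lists as its 8 (highest other 11). The larger camera adjusted p of the cholesterol and fatty acid lists, with the preset correlation, was 5.74e-10 in the real grouping. In the other splits it ran from 0.00352 to 0.880. Both are lists that the real grouping called, and the splits are too few for a share under 0.05. The split with 11 lists set control 1 and both arrays numbered 3 against the rest, and gave 1123 genes at an unadjusted p of 0.05 against 650, which may point to the structure of those arrays. The other 3 splits that kept both arrays numbered 3 together gave 8, 6 and 4 lists, so not every such split reached the real number; with the replicate block 7 lists passed. Of the 4 splits that part every pair, the real one gave 8 lists and the others 6, 4 and 1, while the other 6 splits leave some pair whole.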
